A study of Mus musculus with 2 samples.

How the data were processed

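Total RNA was extracted with Trizol from isolated islets frozen on dry ice, and libraries were built from 1 microgram with a TruSeq RNA kit, per the labels' protocols. Each group, wild type and Brsk2 transgenic, had 1 library, taken from the genotype label. The mice were 10 to 12 weeks old. Whether a library came from 1 mouse or a pool, and whether the kit kept strand, is not given in the sources used here, so antisense and overlapping genes cannot be told apart from their partners.

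The authors deposited raw read counts for 54532 Ensembl gene IDs in each library. The aligner, the counting program and the genome build are not given in the sources used here. Of these IDs, 54495 were found in GENCODE release M21 on GRCm38, and 98.3% of those had the same start and end, so the coordinates printed are those of the count table and were treated as GRCm38. The authors also deposited tables of genes they listed as different, with normalized counts (a signal scale of counts divided by a constant per library, except that 14 listed genes with 0 reads in a library carry 1.39e-17 there, for a reason not given), log2 fold changes and p-values with adjusted p-values. The submitters' processing notes name DESeq2 1.10.1. How a test was made with 1 library per group is not given there. The authors' log2 fold changes differed from those computed here by a median of 0.00 over 52 listed genes with at least 100 reads in each library.

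From the deposited counts, genes with at least 10 reads over both libraries were kept (17709 genes). Libraries were scaled by TMM factors (edgeR 4.0.16 in R 4.3.3; factors 0.987 and 1.01) and counts were expressed as CPM, read counts scaled to the adjusted library size. A read was worth 0.0497 CPM in the wild-type and 0.0586 CPM in the transgenic library. No test of groups was made, since 1 library per group leaves no spread to test against. For each gene the ratio of CPM was given with an exact 95% interval (Clopper-Pearson on the share of its reads in the transgenic library, SciPy 1.17.1). Shares of reads had exact Clopper-Pearson intervals. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. A count of 0 was set against a floor of 3 reads per library and the ratio given as a bound. Its interval was computed from the counts without the floor.

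A gene was counted as higher or lower where its ratio passed 2-fold and its interval excluded 1, and a member of a gene list at 1.5-fold. The 24 gene lists were fixed before the data were examined. For each, the median log2 ratio of measured members was placed among 10000 random lists of the same size, matched in 20 bins of expression. This describes these 2 libraries and is not a test across animals. Named genes followed a rule fixed at the same time: Brsk2, Brsk1 and 7 hormones; the 12 protein-coding genes with at least 100 reads in a library whose interval bound nearest 1 was highest, and the 12 at the other end; in each list the 3 members with the largest absolute log2 ratio and the most abundant one, given at least 100 reads over both libraries; and the 3 genes with the smallest adjusted p-value in each direction of the authors' table. Other genes named as members of small counts were chosen after their values were seen.

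The steps were tested on simulated data: counts for the real genes with 200 planted differences and Poisson sampling error. All planted genes had at least 100 reads over both libraries, so detection among genes with fewer reads was not tested. Of 40 genes planted at 3-fold all 40 were called, as were all 40 at 4-fold and 40 each at the inverse folds, and 26 of 40 planted at 1.5-fold passed the 1.5-fold rule. Intervals held the true ratio of 1 for 95.7% of unchanged genes. They held the planted ratio for 90% (inverse 3-fold) to 100% (3-fold) of planted genes. A planted list of 20 genes at 1.5-fold lay at percentile 100.

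Alternatives planned before the data were examined were DESeq2 size factors (DESeq2 1.42.0), library totals, TMM without hormones and acinar markers, other read minimums, protein-coding genes only, other fold rules and other denominators of the hormone share. Centring of ratios in 10 bins of transcript GC content and 10 of transcript length was added after seeing the data. The figures were drawn with matplotlib 3.10.9, and tables handled with pandas 2.3.3 in Python 3.11.15.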

Results

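RNA of pancreatic islets, the clusters of hormone-secreting cells of the pancreas, was sequenced from male C57BL/6 mice that were either wild type or carried a transgene for over-expression of Brsk2, a serine/threonine kinase of the AMPK-related family. Mice of both genotypes received doxycycline, the drug used to switch on inducible transgenes, in their drinking water for 4 days at 8 to 10 weeks of age. The comparison asked how gene expression in islets differed when Brsk2 was over-expressed. There was 1 library per group, so no spread between animals was measured and no difference below has a replicate check. The wild-type library held 20389499 reads assigned to genes and the transgenic library 16832312, and reads were found for 23584 and 23594 genes. Each ratio is transgenic over wild type in CPM, read counts scaled to library size, and the range in brackets is its 95% interval, which covers counting error only. Members of gene lists are called higher or lower where the ratio passed 1.5-fold and the interval excluded 1.

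Brsk2 (ENSMUSG00000053046, chromosome 7, 141949751 to 142004247, plus strand) was higher in the library labelled transgenic, at 94.3 CPM against 36.4 CPM, a ratio of 2.59 [2.37, 2.83] from 1609 and 732 reads. The counts do not separate reads of the transgene from reads of the endogenous gene. Brsk1, the closest relative of Brsk2, had a ratio of 1.01 [0.868, 1.17]. In the fixed list of AMPK-related kinases without Brsk2, 1 of 20 measured members was at least 1.5-fold higher and 3 were at least 1.5-fold lower. Prkab2, a regulatory subunit of AMPK, had a ratio of 0.468 [0.434, 0.505], and Sik1 had a ratio of 0.598 [0.504, 0.709]. The other lower member was Melk, with 24 and 6 reads, and the higher one was the AMPK catalytic subunit Prkaa2, with 92 and 117 reads; with DESeq2 size factors Prkaa2 no longer passed and 4 were lower. The median log2 ratio of this list was -0.12, at percentile 13.9 of random lists matched on expression.

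Among 17709 genes with at least 10 reads over both libraries, 755 were at least 2-fold higher in the transgenic library and 448 at least 2-fold lower, with an interval that excluded 1. Of these, 511 and 265 were protein-coding. In counts simulated with sampling error alone for this comparison, 81 of 17546 unchanged genes passed the same rule as higher and 71 as lower. The numbers depended on the rule: where the interval itself had to pass 2-fold, 188 genes were higher and 86 lower, and with at least 50 reads 321 were higher and 226 lower. The median log2 ratio over all measured genes was 0.01.

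**Figure D1:**
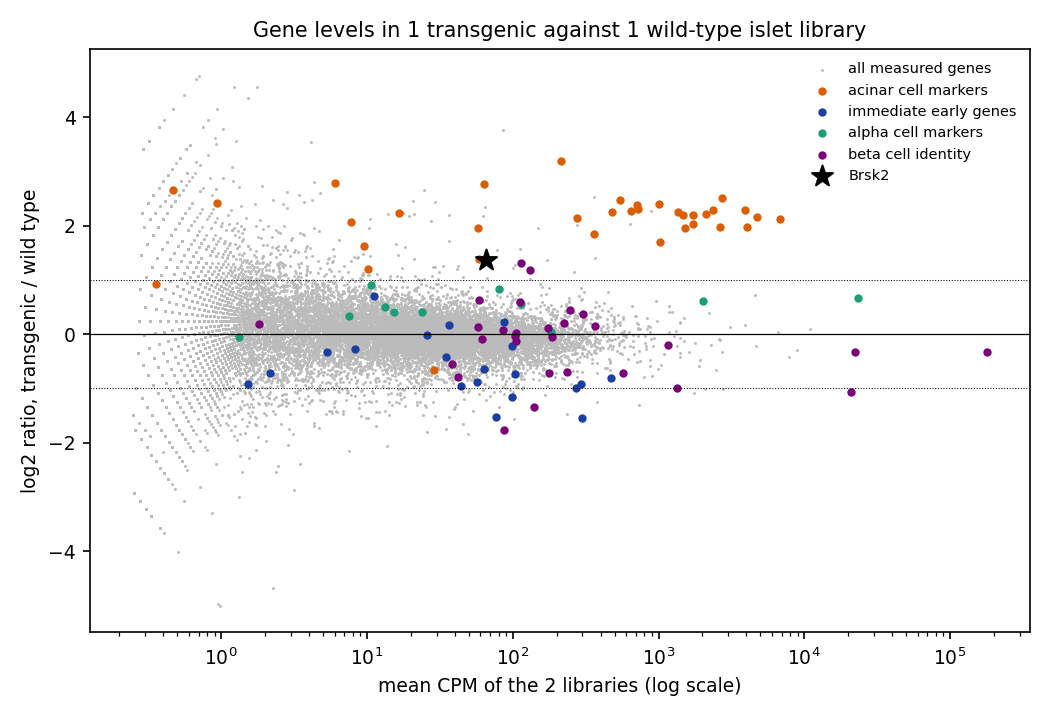
Log2 ratio of transgenic over wild-type CPM (vertical axis) against the mean CPM of both libraries (horizontal axis, log scale) for 17709 measured genes, 1 point per gene, from 1 library per group. Coloured points mark 4 fixed gene lists, the star marks Brsk2 and dotted lines mark 2-fold; acinar markers form a group with a median of 2.20, and immediate early genes lie mostly below 0, with a median of -0.72.

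The insulin genes took a smaller share of the transgenic library and the hormones of the other endocrine cells a larger one. Ins2 accounted for 16.2% of reads against 19.7% in the wild-type library, and Ins1 for 1.37% against 2.81%. Ratios were 0.476 [0.474, 0.478] for Ins1, 0.800 [0.799, 0.802] for Ins2 and 0.799 for Iapp, the amyloid peptide secreted with insulin. By contrast the ratio was 1.59 [1.59, 1.60] for Gcg, the glucagon gene of alpha cells, 1.66 [1.64, 1.67] for Ppy, 1.31 for Sst and 1.15 [1.13, 1.17] for Pyy. The 7 hormone genes together took 23.4% of reads (exact binomial interval 23.4 to 23.4) against 27.3% (27.3 to 27.4). Because Ins1 and Ins2 are close paralogs, reads could have been divided between them in counting.

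Several genes of mature beta cells were lower in the transgenic library, while the members called higher were broad endocrine factors. Of 29 measured members of the beta cell list, 8 were at least 1.5-fold lower, 4 at least 1.5-fold higher and 17 neither. The lower members were Ins1, the cation channel Trpm5 (0.292 [0.268, 0.318]), the secreted peptide Ucn3 (0.392 [0.368, 0.417]), the glucose-6-phosphatase G6pc2 (0.502 [0.492, 0.511]), the incretin receptor Glp1r (0.580), the zinc transporter Slc30a8 (0.605), the transcription factor Mafa (0.605) and the glucose transporter Slc2a2 (0.614). The higher members were the transcription factors Isl1 (2.47 [2.31, 2.64]), Rfx6 (2.28 [2.15, 2.42]), Foxa2 (1.55) and Nkx2-2 (1.502), which other endocrine cells also express. With DESeq2 size factors Nkx2-2 no longer passed 1.5-fold, leaving 3 higher. Pdx1, a transcription factor of beta cells, was neither, at 1.05 [0.981, 1.13]. The list's median log2 ratio was -0.06, at percentile 58.7, and -0.01 after GC and length centring. In these libraries the acinar list described below took 1.57% of wild-type and 7.20% of transgenic reads.

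The medians of alpha cell markers and of delta, gamma and epsilon cell markers both lay above the range of random lists. Of 11 alpha cell markers, 4 were at least 1.5-fold higher and none at least 1.5-fold lower, with a median log2 ratio of 0.50 at percentile 100. Among them, besides Gcg, were the thyroid hormone carrier Ttr (1.53) and the somatostatin receptor Sstr2 (1.88 [1.53, 2.33]). Of 9 delta, gamma and epsilon cell markers only Ppy was called higher, while Ghrl, at 1.525 with an interval that held 1 [0.9952, 2.351], was not; the median was 0.45 at percentile 99.9, with a 95% interval over members from -0.48 to 0.61. The retinol-binding protein gene Rbp4 was at 1.46 [1.39, 1.53] and Etv1 at 1.44 [1.27, 1.63]. Below 1 were the somatostatin receptor Sstr3, at 0.698 [0.667, 0.730], and the ghrelin receptor Ghsr, at 0.719 [0.501, 1.02]. In the list of glucose sensing and insulin secretion machinery, 1 of 31 members was higher, the vesicle GTPase Rab3a (1.651 [1.496, 1.823]), and none lower, with a median of 0.02 at percentile 93.3, and of -0.00 after GC and length centring. Of 17 disallowed and dedifferentiation genes, which mature beta cells keep low, 5 were higher and none lower; Igfbp4 had a ratio of 2.14 [1.49, 3.10] and the endocrine progenitor factor Neurog3 2.11 [1.35, 3.33] from 33 and 59 reads. Mylk (2.01) and Hk2 (1.71) were also among the higher ones. The median of the disallowed and dedifferentiation genes was 0.31 at percentile 93.1, inside the 95% range of random lists. In the same library 11 of 20 fibroblast, stellate and mural cell markers were higher, with a median of 0.70.

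**Figure D2:**
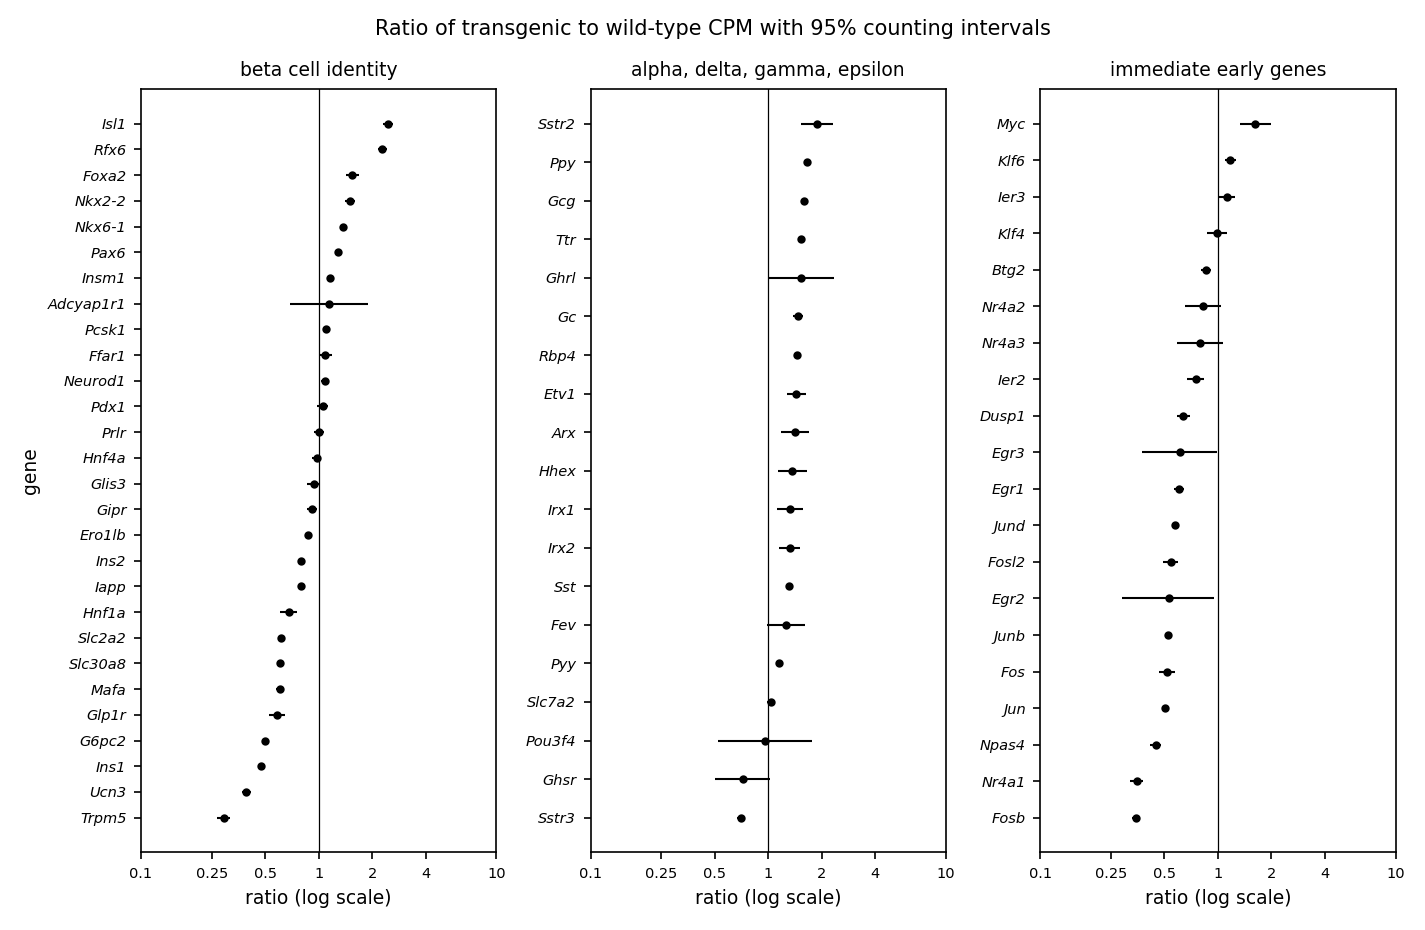
Ratio of transgenic to wild-type CPM (horizontal axis, log scale) for most measured members of the beta cell list, the lists of other endocrine cells and the immediate early gene list, with 95% counting intervals as bars, from 1 library per group. Members of the beta cell list spread from Trpm5 at 0.292 to Isl1 at 2.47, while 12 of 20 immediate early genes lie at least 1.5-fold below 1.

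Genes of the exocrine pancreas were higher in the transgenic library almost without exception. Of 35 acinar cell markers, 33 were at least 1.5-fold higher; Prss1, with 5 and 8 reads, was neither and the transcription factor Bhlha15 was lower (0.632 [0.557, 0.716]). The median log2 ratio was 2.20 at percentile 100. The most abundant member, the chymotrypsinogen gene Ctrb1, had a ratio of 4.33 [4.28, 4.37], the pancreatic lipase gene Pnlip 4.90 [4.83, 4.96], the trypsin inhibitor Spink1 6.83 [6.07, 7.71] and the acinar transcription factor Rbpjl 6.89 [4.69, 10.4]. Amylase and trypsin genes are families of near-identical copies, so their single values are uncertain.

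Among markers of other non-endocrine cells, the medians of the fibroblast, red blood cell and endothelial lists lay outside the range of random lists and the others inside it. Fibroblast, stellate and mural cell markers were higher in 11 of 20 cases and lower in 1 (Cspg4, 0.549), with a median of 0.70 at percentile 100; Col3a1 had a ratio of 3.17 [2.62, 3.84] and Dcn 2.03 [1.67, 2.47]. Red blood cell markers were higher in 4 of 6 cases, at a median of 0.84 and percentile 99.5, with Hba-a1 at 1.962 [1.546, 2.501]; the others were Hba-a2, Hbb-bs and Hbb-bt, and copies of globin genes share reads. Endothelial markers had a median of -0.21 at percentile 1.75, just past a lower end of -0.199. Across all processing settings this median ran from -0.22 to -0.16. None of 14 endothelial markers was called, among them Cldn5 at 0.481 with an interval that reached 1 [0.215, 1.001]. Cldn5 was called lower with DESeq2 size factors. Of 15 B, T and NK cell markers, Ighm (4.60 [4.01, 5.28]) and Igkc (4.66 [3.89, 5.62]) were higher and 2 lower, Ccr7 (0.558) and Trac (15 and 1 reads, 0.0786 [0.00187, 0.511]), with a median of -0.08 at percentile 18.2, and of 0.03 among members with at least 50 reads. The B cell receptor component Cd79a, at 0.768 [0.688, 0.857], did not pass 1.5-fold. Of 14 ductal markers, Muc1 (2.24), Spp1 (1.77) and Tspan8 (1.73) were higher and Onecut2 (0.440) lower, with a median of 0.20 at percentile 94.0. Of 18 macrophage and dendritic cell markers, the lysozyme gene Lyz2 (1.84 [1.51, 2.24]) was higher and Laptm5 (0.553) lower, with a median of 0.19 at percentile 94.0. Of 12 Schwann and neural markers, Cdh19 (3.78), Ngfr (1.72) and Uchl1 (1.64) were higher and Mbp (0.664) and Gfap (0.236, 15 and 3 reads) lower, with a median of 0.27 at percentile 88.1. Only 2 adipocyte markers were measured, with a median of 0.48 at percentile 96.8, and Lpl (1.74) was higher.

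Immediate early genes, which cells switch on rapidly after stimulation, were lower in the transgenic library. Of 20 members, 12 were at least 1.5-fold lower and Myc alone was higher (1.62 [1.33, 1.99]), with a median log2 ratio of -0.72 at percentile 0. Fosb had a ratio of 0.344 [0.329, 0.359], Nr4a1 0.349 [0.320, 0.380], Npas4 0.446 [0.415, 0.479] and Jund, the most abundant, 0.570 [0.553, 0.588]. Acinar markers were higher in the same library, as given above.

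The medians of the unfolded protein and interferon response lists lay below the range of random lists, while most of their members were neither higher nor lower. Of 30 genes of the unfolded protein and integrated stress response, 4 were at least 1.5-fold lower and none higher, with a median of -0.28 at percentile 0.07; Atf5 had a ratio of 0.509 [0.477, 0.542], Atf3 0.591 [0.534, 0.654], Edem1 0.605 and Herpud1 0.643. The chaperone Hspa5, at 0.743 [0.737, 0.748], did not pass 1.5-fold. Of 25 interferon response genes, 3 were lower and none higher, with a median of -0.25 at percentile 0.14, Ddx58 at 0.608 [0.570, 0.648], Oasl2 at 0.615 and Oas1a at 0.665. The list of inflammatory mediators had a median of 0.18 at percentile 98.2, with 3 of 20 higher, Ccl7 (1.98 [1.48, 2.67]), Il1b (1.65) and Ptgs2 (1.56), and 2 lower, Lcn2 (0.595 [0.427, 0.820]) and Tnfaip3 (0.633).

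Of 20 NRF2 antioxidant genes, the cystine transporter Slc7a11 (1.93 [1.42, 2.65]) was higher and Gstm1 (0.626), Nqo1 (0.647), Ftl1 (0.651) and Srxn1 (0.664) were lower (2 with library totals, without Ftl1 and Srxn1), with a median of -0.12 at percentile 14.2, and of -0.18 among members with at least 50 reads. Of 28 nuclear-encoded oxidative phosphorylation genes, Ndufa1 (1.82 [1.67, 1.98]) was higher and none lower, with a median of -0.01 at percentile 82.7, 0.03 with library totals and -0.08 after GC and length centring. Of 13 mitochondrially encoded genes, mt-Co3 (1.58) was higher and mt-Nd5 (0.636), mt-Nd4l (0.657) and mt-Atp8 (0.477) were lower, with a median of -0.20 at percentile 6.68, and of -0.35 after GC and length centring. The median was -0.17 for sterol synthesis and lipogenesis (percentile 4.41; 1 of 25 lower), and -0.11 after centring. The lower member was Hmgcs1, an early enzyme of cholesterol synthesis, at 0.622 [0.597, 0.647] before centring. For cell proliferation the median was -0.06 (percentile 15.9; -0.02 with library totals), with Mcm6 (1.51) and Aurkb (4.13, 4 and 14 reads) higher of 22, none lower, and Top2a at 0.765 [0.583, 0.998].

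**Figure D3:**
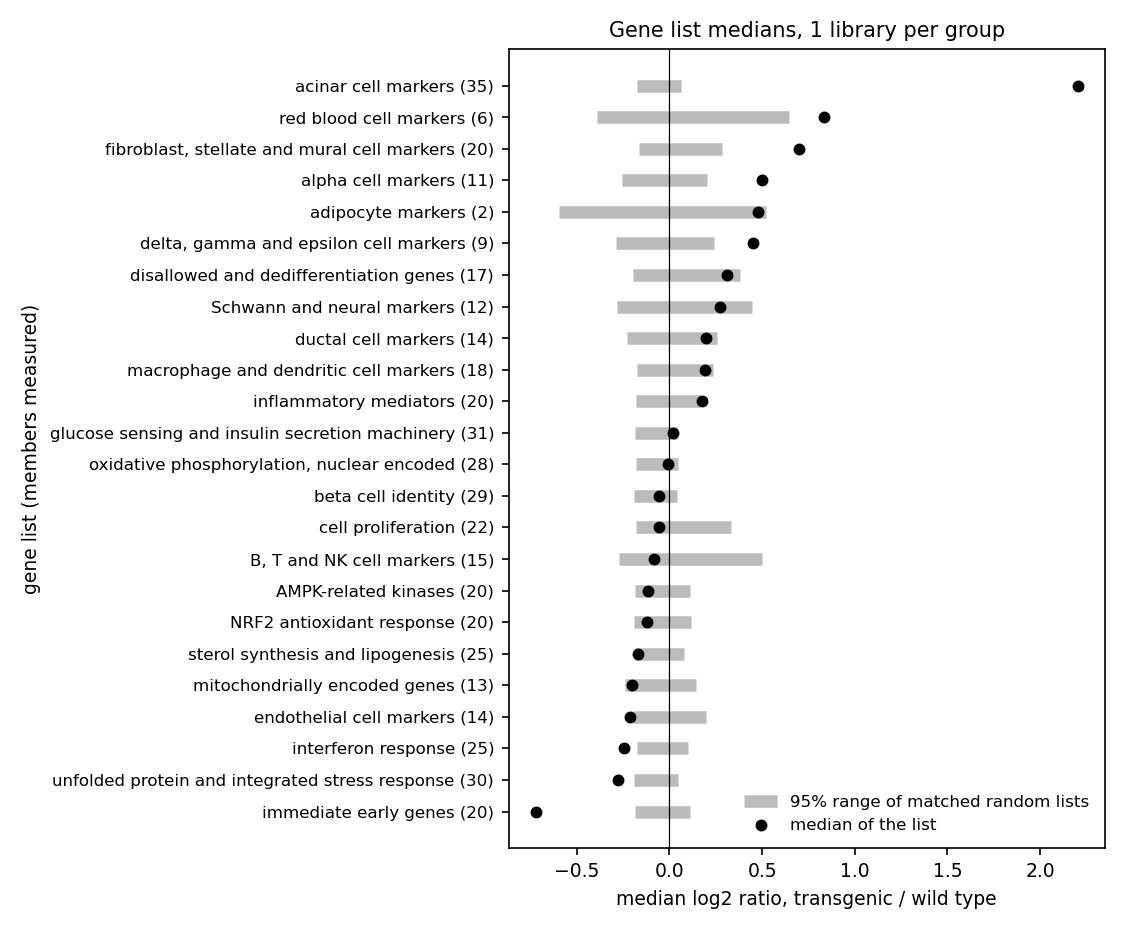
Median log2 ratio of transgenic over wild type (horizontal axis, points) for 24 fixed gene lists, with the number of measured members in brackets, from 1 library per group. Grey bars span the central 95% of medians of 10000 random lists matched on expression; the acinar list at 2.20 and the immediate early genes at -0.72 lie farthest from their bars.

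The 12 protein-coding genes with the highest lower interval bound were mostly exocrine: Amy2a2 (13.6 [11.9, 15.7]), Amy2a5, Amy2a4, Spink1, Try4, Zg16, Clps, Rnase1, Pnlip and the gene listed as 2210010C04Rik, together with Jchain (11.7 [6.61, 22.6]), the joining chain of secreted antibodies, and the fibrinogen gene Fgb (6.34 [5.27, 7.68]). The 12 with the lowest upper bound included Mlph (0.137 [0.0707, 0.244]) and Ppargc1a (0.238 [0.188, 0.299]), a coactivator of mitochondrial gene expression. They also included the stimulus-responsive genes Arc (0.317 [0.282, 0.355]), Fosb and Nr4a1 and the transcription factor Srf (0.359 [0.342, 0.377]). Th, the rate-limiting enzyme of catecholamine synthesis, was at 0.349 [0.307, 0.395], and Trpm5, Fam83g, Prr7, Ccdc85b and T2 completed the group.

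The authors' deposited table listed 108 genes as different between the libraries, 88 higher and 20 lower in the transgenic one. All 108 were called here in the same direction, which rests on the same 2 libraries and is no independent evidence. The genes in the authors' deposited table made up 8.98% of those called here, and included 29 acinar markers, 13 immunoglobulin segments and, from the beta cell list, Trpm5. Brsk2 was not in the authors' deposited table, where the smallest absolute log2 fold change was 1.57. Its smallest adjusted p-values for higher genes belonged to Amy2a2, Amy2a5 and Ltf, and for lower genes to Glycam1, Ccl21a and Mlph. Ltf had 0 wild-type and 60 transgenic reads, at least 18.6-fold higher by the interval limit nearest 1. That limit was computed from the counts without the floor of 3 reads. Glycam1 had 91 wild-type and 0 transgenic reads, at least 20.5-fold lower by the same limit, and Ccl21a 35 and 0 reads, at least 7.63-fold lower. With 1 library per group those p-values do not measure the spread between animals.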

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

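Centring by GC content and length was chosen after the data were seen; the other settings were planned. All 24 list medians stayed within an interval over their members under 3 other scalings, 2 other read minimums and protein-coding genes only. It was the 95% interval of the median, except for the 2 adipocyte markers, where it was their span. Rescaling shifts every median by the same small amount, so staying inside a wide interval is a weak check. Library totals, for example, put the median over all measured genes at 0.04. Under centring all stayed inside except nuclear-encoded oxidative phosphorylation, which went from -0.01 to -0.085. The cause was not tested. The acinar median ranged from 2.11 to 2.24, that of immediate early genes from -0.73 to -0.67 and that of alpha cell markers from 0.50 to 0.54. Counts of higher and lower genes moved by over 1.5 times with the rule: 321 and 226 with at least 50 reads, 1377 and 1043 at 1.5-fold, and 188 and 86 where the interval bound had to pass 2-fold, as fewer or more genes qualify by construction. Among protein-coding genes only, 265 were lower, because the other gene classes were left out. Of the 755 higher and 448 lower genes, 748 and 448 were shared under DESeq2 size factors, 755 and 395 under library totals, and 684 and 424 after centring. Of 131 calls of list members at 1.5-fold, a comparison added after the data were seen, 6 ended with library totals (Srxn1, Ftl1, mt-Nd4l, Egr3, Oas1a and Mbp) and 2 with DESeq2 size factors (Nkx2-2 and Prkaa2), while 5 and 4 were gained. The hormone share became 27.8% and 23.9% of protein-coding reads, and 28.1% and 24.0% without mitochondrially encoded genes, since the denominators are smaller. Of 114 named genes, 19 left their counting interval under library totals and 1 under DESeq2 size factors. Such a scaling multiplies all ratios alike; 2 ratios crossed 1 under library totals, Stk11 (0.983 to 1.01) and Cd74 (0.993 to 1.02), both with intervals that held 1. The depth limits genes of few reads, where 1 read is worth 0.0497 and 0.0586 CPM, and no setting replaces the missing replicates.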

Other observations

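The tests on acinar markers, on dilution, on GC content and length and on beta cell number were chosen after the results were seen; the predictions for heat shock genes, SRF targets and FOXO targets were written before the values of those lists were seen. The prediction for the region around Brsk2 counts as written after, because Cd81, a gene beside Trpm5, had already been seen to be higher, at 2.43 [2.27, 2.60]. For the 3 lists, the demand that the median also pass its random range after GC and length centring was added after their results were seen, and it changed the verdict on heat shock genes. Genes named in this part were chosen after their values were seen.

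Genes of secreted antibodies and of the regenerating islet-derived family were higher in the transgenic library. Of 32 measured immunoglobulin segments, 25 were at least 2-fold higher and 3 at least 2-fold lower, from 531 and 2157 reads in all. Reg3b (5.46 [4.50, 6.66]) and Reg3d (4.62 [3.70, 5.82]) were higher, as were all 4 measured members of the Reg3 family. Of 79 cytosolic ribosomal protein genes, 17 were at least 1.5-fold higher and 2 lower, with a median log2 ratio of 0.34, and of 0.28 after GC and length centring. The metallothionein genes Mt1 (0.496 [0.490, 0.503]) and Mt2 (0.368 [0.294, 0.456]) were lower, as were the cytoskeletal genes Actg1 (0.472 [0.465, 0.480]) and Krt8 (0.494 [0.486, 0.501]).

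Acinar markers were higher by a median log2 ratio of 2.20. Acinar cells or their RNA carried into the transgenic islets are a candidate source. The 10 list members that encode no digestive enzyme had a median of 2.26. The list's most abundant gene, Ctrb1, went from 2566 to 11100 CPM. These genes belong to the list already seen to be higher, so their values cannot decide between sources. Bhlha15 went the other way, at 0.632, and endocrine cells also express it. An effect of the transgene on exocrine tissue cannot be told apart from a difference between isolations, because there was 1 library per group.

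Immediate early genes were lower by a median log2 ratio of -0.72. Dilution by acinar RNA that lowered all other genes alike is argued against. The list lay -0.73 from the median of all measured genes outside the acinar list, a distance that no scaling alters. A dilution that lowers some of the other genes more than others was not tested. A trend with GC content and length is also argued against, since the list's median after centring was -0.67. Different handling of the islets stays open: 17 heat shock genes, which handling stress may also induce, had a median of -0.23, which lay just outside the random range, whose lower end was -0.227, and so met the prediction as first written, but after centring the median of -0.211 lay inside a range ending at -0.213. Of these 17 genes 4 were at least 1.5-fold lower, Hspa1a (0.564), Dnaja1 (0.583), Hspa1b (0.612) and Dnaja4 (0.620), and none was higher. An effect of Brsk2 over-expression also stays open and was not tested.

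Trpm5, Ucn3, G6pc2 and 5 other beta cell genes were lower while Isl1 and Rfx6 were higher. Fewer beta cells alone would lower such genes alike, but the log2 ratios of 21 beta cell members outside the broad endocrine factors had an interquartile range of 0.69 and ran from -1.78 to 0.45. Centring by GC content and length moved the median of the 8 lower genes only from -0.89 to -0.92. These 8 were picked as lower in the same libraries, so their staying low is no independent evidence. A mixture of fewer beta cells with changed expression within them was not tested, and neither the transgene nor a difference between single isolations is excluded.

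As a hypothesis, SRF and MRTF activity, which drives actin and many immediate early genes, may be lower in the transgenic library: Srf, Actg1, Vcl, Zyx and Fhl2 had drawn attention, and 20 other targets had a median log2 ratio of -0.43, below the random range of -0.19 to 0.13, and of -0.36 after centring. None was at least 1.5-fold higher and 5 were lower, with Actb at 0.578 [0.564, 0.592] and Flna at 0.566 [0.516, 0.622]. Mural cells also express several of them, and fewer mural cells are not excluded: the mural marker Cspg4 was lower, at 0.549, while Rgs5 was at 1.04. A second hypothesis, higher FOXO activity, came from Depp1 (2.99 [2.79, 3.20]), Pik3ip1 (2.39), Klhl24 and Txnip. The evidence was slight: 23 other targets had a median of 0.075, past an upper end of 0.0722, with 3 higher and 2 lower, while after centring it was 0.14.

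Th and Trpm5, at 0.349 and 0.292, lie 0.943 and 1.12 Mb from Brsk2 on chromosome 7. A lowering of all genes of that segment is argued against: 81 other measured genes within 2 Mb, without Ins2 (0.800), had a median log2 ratio of 0.0487, at percentile 85.4 of matched random lists, with 5 higher, Cd81 (2.43) among them, and 3 lower at 1.5-fold. At the same threshold 1377 of all 17709 measured genes were higher and 1043 lower, so neither share was larger near Brsk2. A linked difference that raises some genes of the segment and lowers others was not tested and stays open.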
